A study of Mus musculus with 12 samples.

How the data were processed

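RNA-seq was done on total RNA, extracted with TRIzol, from MC38 tumors grown under the skin of C57BL/6 mice (shCtrl and shChrebp, 3 libraries each) and from bone-marrow-derived macrophages (PBS and choline, 3 libraries each). Libraries were made with the VAHTS Universal V6 RNA-seq kit, per the labels' protocols. The genome build was GRCm39, per the submitters' processing notes. The aligner, the counter and any use of strand are not given in the sources used here. For the tumors the authors deposited estimated counts and FPKM values per Ensembl gene, per the file headers. Of the estimated counts 92.0% are whole numbers, and they were rounded for testing. For BMDM the authors deposited FPKM values per gene, without counts in the table used here.

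Samples were grouped by their titles. For BMDM, 2 PBS columns carry the same heading, so they are used as PBS libraries a and b without a replicate number. Tumor genes were named by identifier through GENCODE vM21 names, which gave a symbol to 22219 of 22274 rows, and annotated transcript lengths and biotypes came from the same annotation. It describes another build (GRCm38), so it was used for names, biotypes and lengths, and no coordinates are printed. The deposited symbol column was not used for names. In 1 pair of rows it is exchanged against the identifiers, Mlxipl and S1pr3. This was checked with the gene length implied by each row's counts and FPKM. Of 9592 genes with at least 100 counts in every library, 12 had an implied length outside their annotated transcripts by more than 10%, and 611 of 631 genes with 1 annotated transcript were within 1 base of it. BMDM rows were named by their deposited symbols, and of 18937 gene numbers with a RefSeq record 18925 matched the symbol. BMDM and tumor rows were paired by symbol (14359 pairs).

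The FPKM values of BMDM were whole multiples of 1 read at each gene's length in 19496 of 19496 rows (100%), within a tolerance of 0.1 reads, against 0 of 500 shuffled rows. This gave reads per gene and 34961461 to 35394132 reads per library, against 15844794 to 24181897 counts per tumor library. A further 0.259 to 0.275% of the reads in each library's FPKM scale lay outside the listed rows. The 2 rows without a name took at most 1.4e-05% each and were left out. The 20 most abundant genes took 8.16 to 8.78% of tumor counts and 10.1 to 10.8% of BMDM reads. Replicates differed by more than counting noise, with a chi-square per degree of freedom of 2.00 to 4.95 in tumors and 4.77 to 13.6 in BMDM, so no pair was counted as 1 library deposited again. This does not show separate animals or cultures, since separate preparations of 1 sample would also exceed counting noise. On the principal components of the tumor libraries, PC1 (59.6%) parted the groups and PC2 (15.6%) set shCtrl 1 at 19.0 apart from shCtrl 2 at −8.04 and shCtrl 3 at −14.6. In BMDM, PC1 (81.2%) parted the groups.

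Tumor genes were tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with TMM library sizes, robust dispersion and filterByExpr. BMDM genes were to be tested the same way, but the table holds FPKM. So the alternative fixed for that unit was used, limma-trend (limma 3.58.1) with robust variances on log2(FPKM + 0.1) for genes at 1 FPKM or more in at least 3 libraries. This scale understates the change of low genes. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05 and no minimum fold change. The common biological coefficient of variation was 0.0388 for tumors and 0.0539 for recovered BMDM reads. Gene lists, 41 in all, of pathways and cell type markers were tested with limma's camera on log2 CPM (prior count 2) or log2(FPKM + 0.1), with a preset correlation of 0.01. Lists with at least 5 tested members were tested, two-sided, and adjusted over the lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera also takes its degrees of freedom from the few libraries, so calls can end at an equal or smaller correlation. Shared calls were tested with Fisher's exact test among genes tested in both comparisons. The target gene was compared by an exact binomial test of summed counts, with a 95% interval, and by an exact permutation test.

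The designs, the lists, the rule for named genes and the alternatives were chosen before the data were examined, except where a choice is said to have been made later. Named are Mlxipl and Mlx; the 10 genes with the highest and the 10 with the lowest fold change among called genes with a mean of at least 50 counts or reads and no overlap between groups, leaving out unnamed models, immunoglobulin and T cell receptor segments and ribosomal or pseudogene copies; up to 4 called members of each list with the smallest adjusted p; and Ccl2, Csf1, Arg1, Nos2, Cd274, Cd8a, Ifng, Gzmb, Prf1, Chka and Slc44a1. The text takes them in that order as far as room allows, and some genes that the rule takes are not reported here. A high-ranking model without a symbol is left out. S1pr3, the list members named because they went against their list (Tlr4, Mmp2, Socs3, Irf4, Slc2a3, and Fth1 in BMDM), the genes named as shared between comparisons and the markers of host cells were chosen after their values were seen.

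The gene tests were run on simulated data with 200 changed genes in each of 5 draws. That is far fewer than were called in the real data, so the shares below need not carry over. For tumors (11712 genes), edgeR recovered 60.1, 76.5, 92.2 and 99.2% of genes changed by 0.25, 0.5, 1 and 2 on the log2 scale, and 7.67% of its calls were unchanged genes. For BMDM (9998 genes), limma-trend recovered 35.1, 83.7, 97.5 and 99.1% at those sizes, and 5.39% of its calls were unchanged genes. Camera was run once per comparison on log2 CPM of simulated counts or reads, with the glycolysis list raised by 0.5. In both, it called the changed list and 0 unchanged lists, but genes were drawn independently, so this does not test the preset correlation. The reported BMDM lists use log2(FPKM + 0.1), which was not simulated for lists. The tests of shared calls and of the target gene were not simulated. Alternatives covered normalization (DESeq2 size factors with DESeq2 1.42.0, upper quartile), test (DESeq2 Wald, limma-voom), low-count filters, a fold minimum of 1, non-robust dispersion, a replicate block, leaving out the top 20 genes, protein-coding genes, FPKM with pseudocounts of 0.1 and 1, and leaving out each library. Added after the data were seen were edgeR on the recovered BMDM reads, TMM scaling of FPKM, lists on log2 CPM of the recovered reads and the row described as Mlxipl in place of the row with its identifier. The edgeR test on recovered reads called 6443 of 12276 genes.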

Results

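Gene expression was measured by RNA-seq in 12 mouse libraries that fall into 4 groups of 3. Per the labels, the first pair of groups came from subcutaneous tumors of MC38 cells, a mouse colon adenocarcinoma line, grown in C57BL/6 mice. Most host-cell markers were scarce in these libraries, as given below. The injected cells carried a short hairpin against Chrebp (shChrebp) or a control hairpin (shCtrl). Chrebp, whose gene symbol is Mlxipl, is a glucose-responsive transcription factor that drives lipogenic and glycolytic genes. The second pair came from bone-marrow-derived macrophages (BMDM) that, per the labels, were first exposed to LPS and IFN-γ for 4 h and then received 200 µM choline for 24 h or PBS. Tumor libraries held 15844794, 16614899 and 19177328 counts in shCtrl and 17775253, 24181897 and 16010568 in shChrebp. BMDM libraries held 34995032 to 35394132 reads with PBS and 34961461 to 35371131 with choline, as recovered from the FPKM values. The labels do not say that replicates were separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. Intervals cover counting error only.

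The tumor comparison asked how gene expression differs between MC38 tumors with and without the hairpin against Chrebp. By gene identifier, the hairpin target Mlxipl was at 3, 1 and 1 counts in the shCtrl libraries and at 1, 1 and 2 counts in the shChrebp libraries. Summed, these are 5 and 4 counts, with a rate ratio of 0.713 (95% exact interval 0.141 to 3.31, two-sided exact binomial p = 0.743). An exact permutation test of the 6 libraries gave p = 0.6, where 0.1 is the smallest p that 3 against 3 allow. Mlxipl was near absent already in shCtrl, at 0.189, 0.06 and 0.052 CPM. A change of it was therefore not detectable, and its counts do not check the labels. The deposited table also holds a row whose symbol and description read Mlxipl but whose identifier is that of S1pr3, a receptor for sphingosine 1-phosphate. The row with the Mlxipl identifier is in turn described as S1pr3. These were the 2 rows of 22274 that stood out of identifier order. The row described as Mlxipl held 376, 431 and 501 counts in shCtrl, a mean of 436 ± 62.7 (SD, n = 3), and 190, 293 and 162 in shChrebp, a mean of 215 ± 69.0 (SD, n = 3). Its log2 fold change was −1.20 ± 0.09 (SE), with an adjusted p of 1.30e-12 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Its counts and FPKM values imply a gene length of 4463 bases, that of the single annotated S1pr3 transcript, while the longest of 10 annotated Mlxipl transcripts has 3622. Values are given by identifier throughout, so this decrease is reported for S1pr3. Mlx, the dimerization partner of Chrebp, was higher in shChrebp by a log2 fold change of 0.18 ± 0.07 (edgeR adjusted p = 0.0311). That call held in 14 of 19 other settings, and the adjusted p ranged from 0.0117 to 0.11. It ended with the DESeq2 Wald test (adjusted p = 0.0839) and on leaving out shCtrl 1, shCtrl 2, shChrebp 2 or shChrebp 3, with edgeR adjusted p-values for tumor Mlx of 0.11, 0.0991, 0.0857 and 0.0770.

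**Figure D1:**
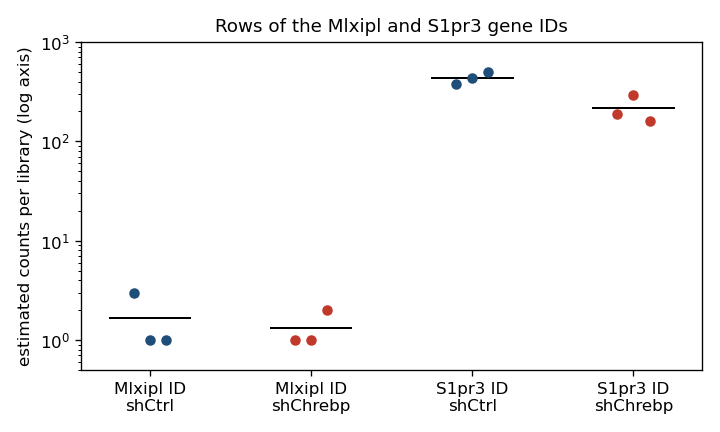
Counts in the 6 tumor libraries for the row with the Mlxipl identifier and for the row with the S1pr3 identifier that the deposited table describes as Mlxipl. Each point is 1 library on an axis of estimated counts, and the group means are 1.67 and 1.33 for the first row and 436 and 215 for the second.

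Interferon-stimulated genes, chemokines that draw myeloid cells and matrix genes were lower in shChrebp tumors, in 25 of 26, 7 of 9 and 15 of 17 tested members. The interferon list was called by camera with an adjusted p of 0.00803 with an estimated correlation, while the other calls were lost, with an adjusted p of 0.0614 for both the chemokine and the matrix list with an estimated correlation. Ifit3, an interferon-induced antiviral protein, went from 152.2 ± 3.18 CPM in shCtrl to 21.5 ± 1.26 CPM in shChrebp (SD, n = 3), a log2 fold change of −2.81 ± 0.05 (SE). Ccl2, the main monocyte-attracting chemokine, went from 233.0 ± 4.59 to 106.7 ± 4.65 CPM, a log2 fold change of −1.13 ± 0.04. Csf1, the growth factor that sustains macrophages, went from 435.0 ± 11.6 to 246.6 ± 10.8 CPM, a log2 fold change of −0.82 ± 0.03. The edgeR adjusted p-values of these 3 genes were 2.64e-27, 1.01e-20 and 2.27e-18.

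Among genes with a mean of at least 50 counts and no overlap between groups, Ifi206 had the lowest log2 fold change, −3.71 ± 0.21, although its reads may be shared within a gene family. Saa3, an acute-phase serum amyloid, followed at −3.63 ± 0.28. Next came Ifit3b at −3.26 ± 0.12, a near-identical copy of Ifit3, so that the split of reads between them is uncertain. The antiviral GTPase Mx1 was at −3.25 ± 0.14 and Cxcl1, which attracts neutrophils, at −3.00 ± 0.11. Apod, a lipid-carrying apolipoprotein, was at −2.95 ± 0.08, and Gbp5, an interferon-induced GTPase, was at −2.84 ± 0.20. Cxcl10, which attracts activated T cells, was at −2.69 ± 0.10, and Zbp1, a sensor of left-handed nucleic acid, at −2.67 ± 0.08. At the other end, Fam180a rose by 1.79 ± 0.17 on the log2 scale. Plin4, a coat protein of lipid droplets, rose from 29.8 to 85.3 CPM, a log2 fold change of 1.52 ± 0.05. The checkpoint receptor gene Havcr2 rose from 12.6 to 30.8 CPM (1.30 ± 0.08) and the metallothionein gene Mt1 from 91.9 to 207.3 CPM (1.17 ± 0.04). Neurl2 was at 1.05 ± 0.20, the kinase gene Mast1 at 1.02 ± 0.18, and Tfrc, the transferrin receptor for iron uptake, at 0.98 ± 0.03. Tmem150a was at 0.97 ± 0.21 and Vmn2r79, a member of a large receptor family whose reads may be shared, at 0.95 ± 0.14. These ranks hold for the scale of counts. On log2(FPKM + 1), which shrinks the changes of low genes, Ifi206 was at −1.68, Gbp5 at −1.48, Mast1 at 0.49 and Tmem150a at 0.51, and Cxcl1 was below Ifi206. Saa3 was below Ifi206 on log2(FPKM + 0.1) and without shChrebp 1, where it was at −4.09. The Tmem150a call ended by limma-trend on log2(FPKM + 0.1) without a filter (adjusted p = 0.0775, in a range from 2.18e-06 over the alternatives).

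Of the 26 interferon-stimulated genes tested, 25 fell in shChrebp and 26 did so adjusted over the list alone, with a median log2 fold change of −1.60. Irf7, a transcription factor that amplifies the response, was at −1.90 ± 0.05 and the antiviral synthetase-like gene Oasl2 at −1.54 ± 0.04. The list was called by camera with an adjusted p of 7.42e-25, and the adjusted p was 0.00803 with an estimated correlation. It was the only tumor list whose call held under that estimate. Among the lists that lost their call, the estimate exceeded the preset of 0.01 for 4. These were matrix (0.015), fatty acid oxidation (0.032), glycolysis (0.450) and mitochondrially encoded genes (0.686). For the others it lay below the preset, as at −0.046 for myeloid chemokines, so a larger correlation does not account for their loss. For matrix it barely exceeded the preset, yet camera's unadjusted p went from 1.52e-06 to 0.00959. With an estimated correlation, camera also takes its degrees of freedom from the few libraries and not from the genes. A lost call under that estimate is therefore not by itself evidence that the genes of a list move together. Myeloid chemokines fell in 7 of 9 tested members, with a median of −1.04. They included Ccl9 (−1.60 ± 0.06) and the monocyte attractant Ccl7 (−0.69 ± 0.05). Camera gave this list an adjusted p of 1.42e-05, and the adjusted p was 0.0614 with an estimated correlation. MHC class I presentation genes fell in 11 of 14, with a median of −0.49. The peptide transporter Tap1 was at −0.98 ± 0.05, the loading factor Tapbp at −0.68 ± 0.04, and the heavy chain genes H2-K1 and H2-D1, which share sequence, at −0.60 ± 0.03 and −0.29 ± 0.03. For this list camera gave an adjusted p of 4.14e-05, and the adjusted p was 0.0614 with an estimated correlation. Inflammasome and Toll-like receptor genes fell in 13 of 18 and rose in 1, Tlr4 (camera adjusted p = 3.01e-04, and adjusted p = 0.0614 with an estimated correlation). Nfkbiz, a nuclear regulator of NF-kappaB targets, was at −1.17 ± 0.06, the inflammatory caspase gene Casp4 at −0.80 ± 0.08 and the pore-forming Gsdmd at −0.50 ± 0.04.

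Extracellular matrix genes fell in 15 of 17 tested members, with a median of −0.24, while the gelatinase gene Mmp2 rose. The fibrillar collagen gene Col3a1 was at −1.40 ± 0.03, Col1a1 at −0.86 ± 0.07 and fibronectin, Fn1, at −0.56 ± 0.03. Of 8 fibroblast markers tested 6 fell, with a median of −0.78, among them the proteoglycan gene Dcn (−1.93 ± 0.16). However, 6 of the 13 markers on the list were under 1 CPM, while Col1a2 was at 787 CPM over the 6 libraries. Which cells the collagen RNA came from was not tested, so these falls do not show fewer fibroblasts. Camera gave adjusted p-values of 1.42e-05 for matrix and 4.07e-04 for fibroblast markers, and each had an adjusted p of 0.0614 with an estimated correlation. Genes of the NRF2 oxidative response fell in 10 of 14 members, and in 11 with 1 higher adjusted over the list alone. Among them, the quinone reductase gene Nqo1 was at −0.92 ± 0.06, the glutathione transferase gene Gstm1 at −0.55 ± 0.05 and the ferritin heavy chain gene Fth1 at −0.39 ± 0.03. The list had a camera adjusted p of 4.08e-04, and the adjusted p was 0.0614 with an estimated correlation. Fatty acid oxidation and PPAR genes fell in 8 of 14 and rose in 2. Cpt1a, which controls fatty acid entry into mitochondria, was at −0.44 ± 0.04 and the fatty acid carrier gene Fabp4 at −1.08 ± 0.17 (camera adjusted p = 0.0296, and adjusted p = 0.210 with an estimated correlation). The fatty acid oxidation call ended without shChrebp 3, with a camera adjusted p of 0.0531 in a range of 8.32e-04 to 0.210 over the alternatives.

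The M1 and M2 macrophage lists were also called lower. However, 13 of 20 M1 genes and 14 of 23 M2 genes were under 1 CPM, and the macrophage gene Adgre1 was at 0 to 1 counts. These calls therefore do not show a change of macrophage state. Of 7 M1 genes tested 6 fell and Socs3 rose. Ptgs2, the inducible cyclooxygenase, was at −0.85 ± 0.03, the transcription factor gene Irf1 at −0.57 ± 0.05 and the inducible nitric oxide synthase gene Nos2 at −0.53 ± 0.11. Of 10 M2 genes 6 fell and Irf4 rose, a call that held in 11 of 17 alternatives (adjusted p from 0.0271 to 0.127 with edgeR, DESeq2 or limma) and ended without shCtrl 1 or 3, without shChrebp 2 or 3, and with the DESeq2 Wald test or FPKM without a filter. Among them, the secreted phosphoprotein gene Spp1 was at −1.15 ± 0.04 and the growth regulator Myc at −0.54 ± 0.04. Camera gave adjusted p-values of 0.00723 and 0.0194, and these became adjusted p = 0.118 and adjusted p = 0.143 with an estimated correlation. Immune checkpoint genes fell in 6 of 8 members, including Cd47, a signal against phagocytosis, at −0.63 ± 0.04 and the costimulatory receptor gene Tnfrsf9 at −0.82 ± 0.12. Cd274, the gene of PD-L1, went from 5.02 ± 0.73 to 2.70 ± 0.38 CPM (−0.88 ± 0.19, and −0.45 on log2(FPKM + 1)), while Havcr2 rose as above. Camera gave an adjusted p of 0.0256, and the adjusted p was 0.152 with an estimated correlation. The checkpoint call ended without a low-count filter (camera adjusted p = 0.0779) and on leaving out shCtrl 1, shCtrl 3, shChrebp 2 or shChrebp 3, with camera adjusted p-values of 0.0982, 0.122, 0.0918 and 0.0712. Over all alternatives it ranged from 5.89e-04 to 0.152.

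Called higher in shChrebp were the hypoxia, glycolysis and mitochondrially encoded lists. Hypoxia-response genes rose in 8 of 16 members, 9 adjusted over the list alone, and fell in 2. They included Bnip3, a mitophagy receptor, at 0.67 ± 0.04, Ndrg1 at 0.54 ± 0.03 and the disulfide oxidase gene Ero1l at 0.46 ± 0.03. For this list camera gave an adjusted p of 0.0336, and the adjusted p was 0.154 with an estimated correlation. The hypoxia call ended without shChrebp 1 or shChrebp 3, with camera adjusted p-values of 0.0524 and 0.0541 in a range of 5.89e-04 to 0.154. Glycolysis genes rose in 9 of 18 members, 11 adjusted over the list alone, and fell in 2, with small changes such as 0.23 ± 0.03 for the aldolase gene Aldoa and 0.20 ± 0.03 for Tpi1. The list had a camera adjusted p of 0.0482, and the adjusted p was 0.552 with an estimated correlation. That call held on leaving out shChrebp 3 (0.0192). It ended without shCtrl 1, 2 or 3, with camera adjusted p-values of 0.0682, 0.0918 and 0.0624, without shChrebp 1 or 2, at 0.0554 and 0.108, and with a replicate block, at 0.0789. By fry, which tests whether a list moves on balance, it was 0.0504. Mitochondrially encoded genes rose in 6 of 13, among them mt-Co3 (0.17 ± 0.04) and mt-Co2 (0.14 ± 0.03), whose nuclear copies make them uncertain. Camera gave an adjusted p of 0.0277, and the adjusted p was 0.544 with an estimated correlation. The mitochondrial call ended without shCtrl 2, shCtrl 3 or shChrebp 2, with camera adjusted p-values of 0.0532, 0.0930 and 0.0876, and by fry (0.127), in a range of 0.00112 to 0.544.

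The list of known Chrebp targets was not called, with 2 members higher and 6 lower of 17 (camera adjusted p = 0.214). Txnip, a glucose-induced inhibitor of thioredoxin, fell from 37.0 ± 3.32 to 14.1 ± 0.44 CPM (−1.39 ± 0.08). The elongase gene Elovl6 rose (0.39 ± 0.04), and the sugar-metabolism genes Tkfc (−0.53 ± 0.09) and Taldo1 (−0.24 ± 0.04) fell. The choline and phospholipid list was not called either, with 5 higher and 8 lower of 25 (camera adjusted p = 0.294). The choline transporter gene Slc44a1 fell from 152.1 ± 6.28 to 127.9 ± 4.27 CPM (−0.25 ± 0.04, edgeR adjusted p = 7.58e-06) and Slc44a2 fell too (−0.51 ± 0.05). Pcyt2 and Pcyt1a, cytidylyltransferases of phospholipid synthesis, rose by 0.39 ± 0.06 and 0.27 ± 0.04. Chka, the first enzyme of phosphatidylcholine synthesis, was at 21.4 ± 1.67 CPM in shCtrl and 20.8 ± 0.72 CPM in shChrebp (−0.04 ± 0.08, edgeR adjusted p = 0.706). Fry, which tests whether a list moves on balance and does not compare it with other genes, called both lists lower, with an adjusted p of 0.00183 for Chrebp targets (range up to 0.566 over the alternatives) and 0.00553 for choline and phospholipid genes (up to 0.489).

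Other lists were not called. Members higher and lower were 10 and 5 of 22 for cholesterol synthesis (camera adjusted p = 0.0746, with Idi1 and Mvd both at 0.53), 9 and 4 of 26 for cell cycle, 7 and 3 of 15 for lysosome, and 2 and 4 of 13 for LXR-driven cholesterol efflux (Abca1 at −1.93 ± 0.11, and at −0.93 on log2(FPKM + 1)). They were 4 and 1 of 20 for nuclear oxidative phosphorylation genes, 2 and 6 of 19 for ATF4 and unfolded protein stress, 6 and 4 of 16 for immediate early genes, 1 and 3 of 24 for ribosomal proteins, and 4 and 4 of 19 for one-carbon metabolism. The neutrophil list had 0 higher and 1 lower of 5, and the epithelial and erythroid lists had 0 called genes of 5 and 6. Camera adjusted p-values of these lists other than cholesterol synthesis lay between 0.189 and 0.599. Adjusted over the list alone, the counts higher and lower became 8 and 3 for lysosome, 3 and 4 for efflux, 5 and 6 for one-carbon metabolism and 0 and 0 for ribosomal proteins, and those of every other tested list not given its own such count above did not change. The cholesterol synthesis list was called higher without a low-count filter (camera adjusted p = 0.0415), without shChrebp 3 (0.0406) and by fry (0.00355), in a range up to 0.346 over the alternatives. Fry also called cell cycle, immediate early and lysosome genes higher and efflux and ATF4 stress genes lower, with adjusted p-values of 0.00183 to 0.0361, in a range up to 0.576 over the alternatives. The calls of Atp5f1 and Uqcrb in oxidative phosphorylation each ended under 2 or more alternatives. For immediate early genes the median was above 0 and the mean below it.

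Most single markers of leukocytes were scarce in the tumor libraries, with 62 of 77 under 1 CPM in shCtrl and 4 over 10 CPM (Fscn1, Cd68, Cd14 and Zbtb46). Dendritic markers summed to 214.3 ± 7.07 CPM in shCtrl and 179.3 ± 5.39 CPM in shChrebp, with Fscn1, an actin-bundling protein, at 184 CPM over the 6 libraries, and macrophage and monocyte markers to 53.4 ± 3.32 and 40.1 ± 2.14 CPM. Endothelial markers summed to 9.10 ± 1.28 and 5.84 ± 0.793 CPM, fibroblast markers to 1690 ± 21.0 CPM in shCtrl and 1105 ± 10.5 CPM in shChrebp and keratinocyte markers to 141.6 ± 5.58 and 119 ± 4.50 CPM (SD, n = 3). The pan-leukocyte gene Ptprc was at 0.352 ± 0.078 CPM in shCtrl and 0.393 ± 0.147 CPM in shChrebp (SD, n = 3), or 4 to 11 counts per library. The macrophage gene Adgre1 was at 0 to 1 counts, the T cell gene Cd3e at 0 in all 6 libraries, and the endothelial gene Pecam1 at 7 to 18. Cd8a, Ifng and Gzmb were listed at 0 counts in all 6, Arg1 at 0 to 1 and Prf1 at 0 to 2. Hbb-bs, a beta-globin gene with near-identical copies, was at 14.67 ± 3.03 and 16.98 ± 1.33 CPM. With fewer than 5 tested members, some lists were not tested as lists. Among them, macrophage and monocyte markers had 2 of 4 lower (Cd68, at −1.10 ± 0.08, and Mpeg1, at −1.96 by edgeR and −1.29 on log2(FPKM + 0.1) without a filter). The MHC class II presentation list had 3 of 4 lower (Cd74, Ctsl and H2-DMa). Lymphoid chemokines had 3 of 3 lower (Ccl5 at −3.13 ± 0.31), a list called lower where no low-count filter let it be tested (camera adjusted p = 5.95e-04). Keratinocyte markers were lower in 2 of 4 (3 adjusted over the list alone), endothelial markers in 1 of 3 (2 over the list alone) and dendritic markers in 1 of 2 (2 over the list alone). Adipocyte and cytotoxic markers were lower in 1 of 2 each, mast cell markers in 1 of 1, and skeletal muscle markers were higher in 1 of 3. The muscle gene is Mylpf, whose groups overlapped and whose call held in 10 of 19 alternatives (edgeR adjusted p = 0.0283, 0.0137 to 0.211 over the alternatives), ending among others without shCtrl 2, shCtrl 3, shChrebp 1 or shChrebp 2. The endothelial gene is Vwf, whose call held in 11 of 17 (edgeR adjusted p = 0.0208, 0.0190 to 0.23), ending among others without shCtrl 3 or any 1 shChrebp library. No called gene stood among the 2 B and plasma cell markers, the 1 NK marker or the 1 T cell marker tested. In shCtrl 1 the epithelial genes stood apart from the other tumor libraries. Krt8 had 341 counts there against 53 and 31 in the other shCtrl libraries and 35, 43 and 38 in shChrebp, and Epcam had 140 against 17, 11, 10, 11 and 6.

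In the tumor comparison 4505 of 11780 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 2189 higher and 2316 lower in shChrebp. Most changes were small, with a median absolute log2 fold change of 0.26 among called genes. A change of 1 or more on the log2 scale was reached by 351 called genes, 31 higher and 320 lower. The groups did not overlap for 5610 genes (47.6%), where chance gives 10%. Without shCtrl 1, 4334 genes were called. Of 28 lists tested, camera called 14, 3 higher and 11 lower. Other splits of the 6 libraries gave up to 7, but each keeps part of the group difference, so they give no null for this count.

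**Figure D2:**
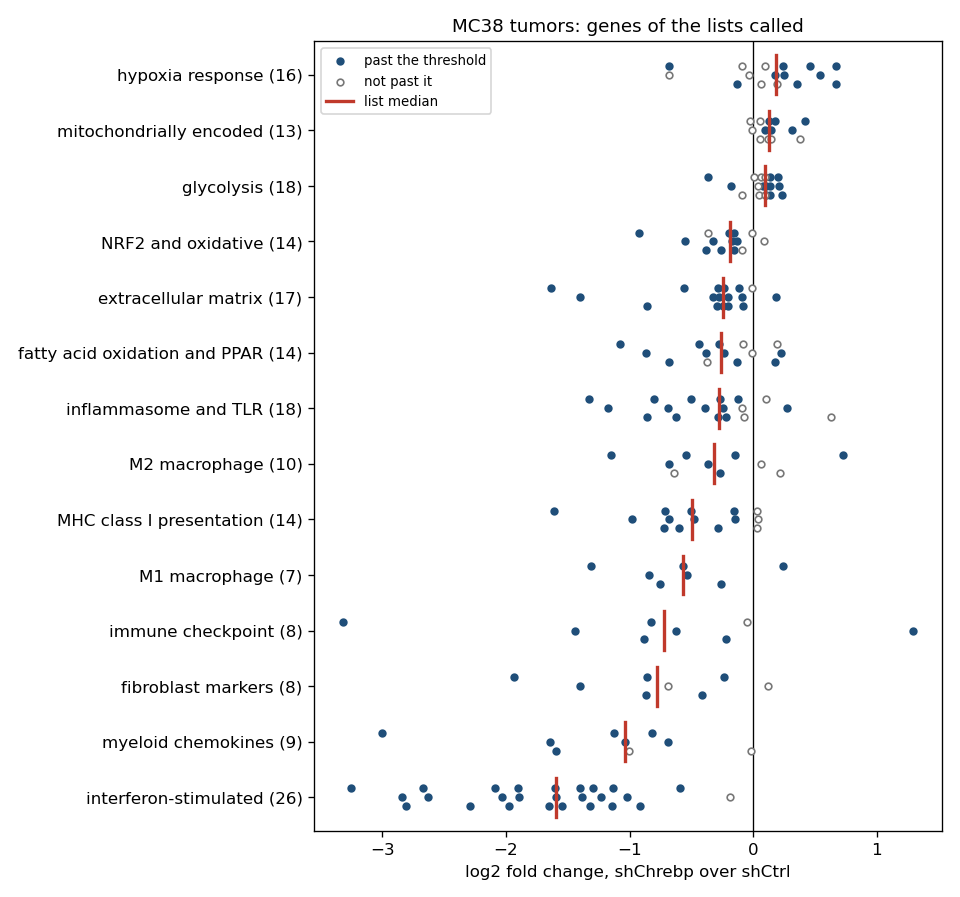
Log2 fold changes (shChrebp over shCtrl) of the tested members of the 14 gene lists called in the tumor comparison, 1 point per gene and a bar at the list median. The interferon-stimulated list lies farthest below 0, with a median of −1.60.

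The BMDM comparison asked what added choline does to gene expression in macrophages that the labels describe as pretreated with LPS and IFN-γ. The interferon-induced genes Ifit3, Cxcl9 and Gbp2 were at 1 to 7, 0 to 1 and 5 to 27 reads in the 6 libraries. The MHC class II gene H2-Aa was at 0 to 3 reads. These genes gave no sign of the labelled IFN-γ exposure. The inducible genes Nos2 and Cxcl10 were expressed with PBS, at 143.2 and 15.5 FPKM. Other members of the interferon and MHC class II lists were expressed too, with Isg15, Oas1a and Cd74 at 20.95, 11.59 and 297.9 FPKM with PBS. Of the 24 interferon-list genes with a row, 12 were under 1 CPM over the 6 libraries. Without macrophages that were not exposed, the pretreatment label could not be checked. With choline, genes of cholesterol synthesis, cell division, glycolysis and the hypoxia response were lower, and lysosomal and inflammasome genes were higher. Of these lists, the cholesterol synthesis call by camera held with an estimated correlation (adjusted p = 0.0461), and the others were lost, with an adjusted p of 0.247 for cell cycle, 0.644 for glycolysis, 0.439 for hypoxia, 0.247 for lysosome and 0.449 for inflammasome genes with an estimated correlation. Il23a, a subunit of an inflammatory cytokine, rose from 5.38 ± 0.44 to 37.3 ± 2.63 FPKM (SD, n = 3), a log2 fold change of 2.77 ± 0.07 (SE) on the log2(FPKM + 0.1) scale that all BMDM fold changes use. Adm, a vasodilator peptide induced by low oxygen, fell from 17.4 ± 2.85 to 2.53 ± 0.40 FPKM (−2.74 ± 0.14). The limma adjusted p-values of these 2 genes were 2.40e-08 and 8.75e-07.

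Among genes with a mean of at least 50 reads and no overlap between groups, Il23a had the highest fold change. Car6, a secreted carbonic anhydrase, followed at 2.62 ± 0.06, and then came Csf1 at 2.35 ± 0.15, from 0.331 ± 0.073 to 2.08 ± 0.06 FPKM. The mitochondrial thioesterase gene Acot2 was at 2.12 ± 0.09 and the serum amyloid gene Saa3 at 2.12 ± 0.08, from 46.1 to 199.7 FPKM. Bach2os was at 2.05 ± 0.20, which is uncertain because it lies antisense to another gene and no use of strand in counting is stated. Mfsd7a and Sh2d6 were both at 1.97, with SEs of 0.21 and 0.08. Eda2r, a receptor of the TNF receptor family, was at 1.96 ± 0.08 and Avil, an actin-binding protein, at 1.89 ± 0.07. The lowest value was that of Selenbp1, a methanethiol oxidase, which fell from 16.4 ± 2.56 to 1.47 ± 0.39 FPKM (−3.41 ± 0.18). After Adm came Mgarp, a mitochondrial protein, at −2.38 ± 0.33, the fractalkine receptor gene Cx3cr1 at −2.23 ± 0.07 and Ocstamp, a factor of osteoclast fusion, at −2.12 ± 0.19. The cytidine deaminase gene Cda was at −1.92 ± 0.21 and the nucleotide receptor gene P2ry6 at −1.87 ± 0.19. Kbtbd11 was at −1.84 ± 0.07, and Sh2d5 and the small GTPase gene Rab15 were at −1.64, with SEs of 0.12 and 0.07. These ranks depend on the pseudocount. With a pseudocount of 1, Csf1 was at 1.21, below Acot2 at 1.93, and Mfsd7a was at 0.93, Mgarp at −1.35, Ocstamp at −1.03, P2ry6 at −1.13 and Sh2d5 at −0.84. With limma-voom on recovered reads Csf1 was at 2.65, above Car6 at 2.62.

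Cholesterol synthesis genes fell in 22 of 22 tested members, with a median of −0.61. The sterol dehydrogenase gene Nsdhl was at −0.86 ± 0.04 and the squalene epoxidase gene Sqle at −0.74 ± 0.04. Camera gave an adjusted p of 5.50e-10, and the adjusted p was 0.0461 with an estimated correlation, the only BMDM list whose call held under that estimate. Cell cycle genes fell in 26 of 26, with a median of −0.47, including the replication helicase genes Mcm6 (−0.94 ± 0.05), Mcm7 (−0.90 ± 0.05) and Mcm4 (−0.80 ± 0.04) and the mitotic cyclin gene Ccnb1 (−0.58 ± 0.04). For this list camera gave an adjusted p of 4.41e-10, and the adjusted p was 0.247 with an estimated correlation. Glycolysis genes fell in 17 of 21, 18 adjusted over the list alone, and rose in 1, the glucose transporter gene Slc2a3, a call that held in 13 of 18 alternatives (limma adjusted p = 0.0299, 0.0148 to 0.121 over the alternatives) and ended without a low-value filter and without PBS replicate 1, the PBS library called b, or choline replicate 1 or 2. Pfkl and Pfkfb3, of the phosphofructokinase step, were at −1.22 ± 0.05 and −1.20 ± 0.06, Tpi1 was at −1.01 ± 0.04 and the glucose transporter gene Slc2a1 at −0.89 ± 0.04. The list had a camera adjusted p of 3.03e-08, and the adjusted p was 0.644 with an estimated correlation. Hypoxia-response genes fell in 13 of 15, with a median of −0.79, among them Bnip3 (−1.26 ± 0.07), Higd1a (−0.89 ± 0.05) and Ddit4 (−0.79 ± 0.04). Camera gave an adjusted p of 8.40e-07, and the adjusted p was 0.439 with an estimated correlation.

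NRF2 oxidative genes fell in 8 of 12, 9 adjusted over the list alone, and rose in 1, Fth1. The heme oxygenase gene Hmox1 was at −1.37 ± 0.06, the glutathione synthesis gene Gclm at −0.94 ± 0.05, the glutathione reductase gene Gsr at −0.61 ± 0.04 and the peroxiredoxin gene Prdx1 at −0.47 ± 0.04. For this list camera gave an adjusted p of 0.00426, and the adjusted p was 0.502 with an estimated correlation. Lysosome and phagocytosis genes rose in 13 of 17 and fell in 0, with a median of 0.32. The Fc receptor genes Fcgr1 and Fcgr2b were at 1.72 ± 0.05 and 0.73 ± 0.05, the lysosomal glycoprotein gene Gpnmb at 0.77 ± 0.05 and the protease gene Ctsz at 0.45 ± 0.04. The list had a camera adjusted p of 1.70e-04, and the adjusted p was 0.247 with an estimated correlation. Inflammasome and Toll-like receptor genes rose in 14 of 20, 16 adjusted over the list alone, and fell in 2. Casp4, which senses cytosolic LPS, was at 1.87 ± 0.05, the adaptor gene Myd88 at 0.62 ± 0.04, Nfkbiz at 0.57 ± 0.04 and the inflammasome sensor gene Nlrp3 at 0.53 ± 0.05. Camera gave an adjusted p of 8.22e-04, and the adjusted p was 0.449 with an estimated correlation.

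**Figure D3:**
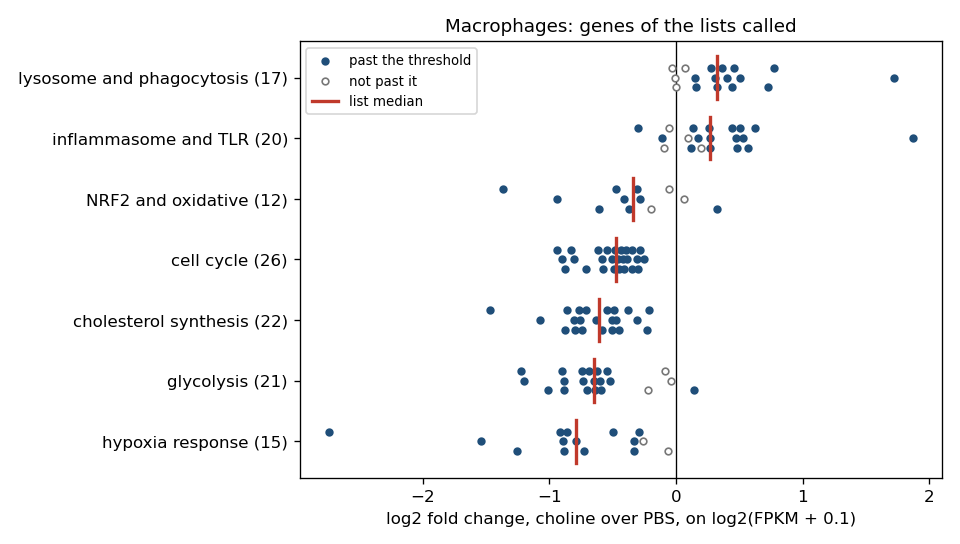
Log2 fold changes (choline over PBS, on log2(FPKM + 0.1)) of the tested members of the 7 gene lists called in BMDM, 1 point per gene and a bar at the list median. The lysosome and inflammasome lists lie above 0, and the other called lists lie below it.

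The choline and phospholipid list was not called, with 10 members higher and 6 lower of 21 (7 lower adjusted over the list alone, camera adjusted p = 0.569). Chka rose from 3.74 ± 0.02 to 5.54 ± 0.13 FPKM (0.55 ± 0.06, limma adjusted p = 3.66e-05), and the choline transporter gene Slc44a1 rose from 14.1 ± 1.02 to 18.7 ± 0.88 FPKM (0.40 ± 0.06, limma adjusted p = 3.63e-04). Cept1, a choline and ethanolamine phosphotransferase, rose by 0.63 ± 0.05 and the acyltransferase gene Lpcat2 by 0.41 ± 0.05, while Pcyt2 fell (−0.97 ± 0.04). Chrebp targets were not called, with 4 higher and 8 lower of 16 (10 lower adjusted over the list alone, camera adjusted p = 0.0720). The Chrebp target list was called lower without a low-value filter (camera adjusted p = 0.0356) and by fry, which does not compare a list with other genes (0.00123), in a range up to 0.871 over the alternatives. Fry also called the choline and phospholipid list higher (adjusted p = 0.00259, in a range up to 0.871). Txnip rose (1.07 ± 0.04), and the desaturase genes Scd1 (−1.04 ± 0.04) and Scd2 (−0.97 ± 0.03) and the pentose phosphate gene Pgd (−1.01 ± 0.04) fell. Mlx fell slightly (−0.20 ± 0.06, limma adjusted p = 0.0120). Mlxipl, Cd8a, Ifng and Gzmb were not analysed here in BMDM.

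The macrophage polarization lists moved both ways and were not called. M1 genes had 6 higher and 6 lower of 14. Beside Il23a, the costimulatory gene Cd40 rose (1.18 ± 0.07), while the cytokine gene Il1b (−1.39 ± 0.10) and Nos2, from 143.2 ± 5.48 to 94.6 ± 6.01 FPKM (−0.60 ± 0.05), fell. M2 genes had 3 higher and 4 lower of 9. Arg1 was at 4, 2 and 12 reads with PBS and at 0 in the choline libraries, under the FPKM minimum, and without that minimum it passed narrowly (limma adjusted p = 0.0489). Prf1 was at 0 to 1 reads. Cd274 rose from 27.8 ± 0.69 to 42.5 ± 1.26 FPKM (0.61 ± 0.04, limma adjusted p = 2.31e-06). Myeloid chemokines had 4 higher and 4 lower of 11. Ccl2 fell from 668.7 ± 19.7 to 505.8 ± 11.2 FPKM (−0.40 ± 0.03, limma adjusted p = 9.80e-06) and Mif fell too (−0.50 ± 0.03), while Cxcl2 (0.56 ± 0.03) and Ccl9 (0.52 ± 0.03) rose. Interferon-stimulated genes had 3 higher and 3 lower of 9, and macrophage and monocyte markers 4 higher and 2 lower of 10.

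Further lists not called had these numbers of members higher and lower. They were 0 and 7 of 20 for nuclear oxidative phosphorylation (camera adjusted p = 0.159, and called lower without a low-value filter at 0.0356 and by fry at 0.0435, in a range up to 0.985), 3 and 5 of 14 for MHC class I, 4 and 2 of 6 for immune checkpoint, 5 and 9 of 18 for one-carbon metabolism, and 7 and 5 of 18 for ATF4 and unfolded protein stress. In that stress list the phosphatase regulator Ppp1r15a rose (1.10 ± 0.04) and the chaperone-related genes Sdf2l1 (−1.02 ± 0.04) and Creld2 (−0.94 ± 0.05) fell. The numbers were 5 and 4 of 13 for immediate early genes, 7 and 5 of 15 for LXR-driven efflux, 3 and 4 of 14 for fatty acid oxidation, 0 and 2 of 13 for mitochondrially encoded genes and 1 and 1 of 24 for ribosomal proteins. Camera adjusted p-values of all the lists not called other than Chrebp targets and oxidative phosphorylation lay between 0.5002 and 0.977. Of these and the polarization, chemokine and macrophage lists, fry called MHC class I and efflux genes lower and checkpoint, M1, M2, macrophage and myeloid chemokine genes higher, with adjusted p-values of 0.00489 to 0.0234, in a range up to 0.985 over the alternatives. Adjusted over the list alone, the counts became 6 and 4 for immediate early genes, 8 and 5 for efflux, 0 and 1 for mitochondrially encoded genes and 0 and 0 for ribosomal proteins. The median, mean and test did not all share a sign for efflux, fatty acid oxidation, checkpoint, interferon, M1, macrophage, mitochondrial and myeloid chemokine genes. Lists with fewer than 5 tested members were not tested as lists. Among these, the MHC class II presentation list had 3 of 3 members higher. They were the invariant chain gene Cd74 (0.42 ± 0.03) and the protease genes Ctsl (0.30 ± 0.03) and Ctss (0.29 ± 0.04). No gene of a class II chain was tested, and 8 of the 12 members were under 1 CPM of recovered reads. The list was called higher where more members were tested, with camera adjusted p = 0.0247 without a low-value filter and 0.0200 on recovered reads, a setting added after the data were seen. Lymphoid chemokines were higher in 2 of 2 (Cxcl10 at 1.18 ± 0.08), and neutrophil markers were higher in 2 and lower in 1 of 3. Fibroblast, T cell and cytotoxic markers were higher in 1 of 1 each, and endothelial and dendritic markers were lower in 1 of 1 each. The cytotoxic gene is Ccl5, also 1 of the 2 lymphoid chemokines, whose call held in 13 of 18 alternatives (limma adjusted p = 0.0263, 0.00469 to 0.0971). It ended without a low-value filter, PBS replicate 1, the PBS library called a, or choline replicate 1 or 2. The single-gene calls of ND4L in the mitochondrial list and Rpl30 in the ribosomal list held in 13 and 11 of 18. No gene was called among 2 skeletal muscle markers, 1 adipocyte marker and 1 matrix gene (1 higher adjusted over the list alone). No member of the B and plasma cell, erythroid, keratinocyte, mast cell, NK or epithelial lists was tested.

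With choline, 5754 of 10028 tested genes passed an adjusted p of 0.05 in limma's trend test with Benjamini-Hochberg adjustment, 2824 higher and 2930 lower. The median absolute log2 fold change of called genes was 0.34. A change of 1 or more on the log2 scale was reached by 218, 114 higher and 104 lower. The groups did not overlap for 6426 genes (64.1%), where chance gives 10%. Of 24 lists tested, camera called 7, 2 higher and 5 lower. Of the 10 splits of the 6 libraries, the real one included, 6 had at least 7 and the highest other had 8. Each other split mixes the groups unequally and so keeps part of the choline difference. The splits therefore give no null for this count.

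The series title joins Chrebp in the tumor, choline and macrophages, so the genes moved in both comparisons were counted, with no library shared between them. Among genes called lower in both were the cytokine gene Lif (−0.96 in tumors), the urokinase gene Plau and the immunoproteasome gene Psmb8 (−0.71 in tumors). Among those called higher in both were the transporter gene Slc38a7 (0.60 in tumors, 0.70 in BMDM) and the lysosomal galactosidase gene Gla. Saa3, Cxcl10 and Txnip were lower in shChrebp tumors and higher with choline, while Mt1, Bnip3, Tfrc and Idi1 were higher in shChrebp tumors and lower with choline. Of 9024 genes tested in both, 557 were higher in both where 505 were expected for independent lists, and 560 were lower in both where 484 were expected. One-sided Fisher's exact tests gave p = 0.00139 and p = 3.24e-06, or 0.00278 and 1.29e-05 after Benjamini-Hochberg adjustment over 4 tests. These tests treat genes as independent and as equally likely to be called. Genes that move together or differ in level are neither, so the p-values may be too small. The excess of genes lower in both passed in 18 of 18 alternatives (exact test, adjusted p from 5.24e-08 to 0.00132) and that of genes higher in both in 17 of 18 (8.25e-15 to 0.0532), the exception being without PBS replicate 1 (0.0532). By the same exact test, opposite pairs numbered 550 for tumor higher and BMDM lower, against 563 expected (p = 0.772, adjusted 0.772), and 462 for tumor lower and BMDM higher, against 434 expected (p = 0.0450, adjusted 0.0600). Without a low-count filter, tumor higher and BMDM lower numbered 589, against 460 expected (adjusted exact p = 9.36e-13, in a range up to 0.968 over the alternatives). The class of tumor lower and BMDM higher passed in 9 of 18 alternatives, with adjusted exact p-values from 0.00795 to 0.483. These were DESeq2 size factors (0.0335), edgeR on recovered reads (0.0344) and leaving out shCtrl 2 (0.0308), shCtrl 3 (0.0393), shChrebp 1 (0.0227), shChrebp 3 (0.0103), PBS replicate 1 (0.00795), the PBS library called a (0.0129) or choline replicate 3 (0.0367). In total 1117 genes shared a direction, against 989 expected, and 1012 went opposite ways, against 997 expected. Of the 2129 genes called in both, 52.5% shared a direction (two-sided Fisher's exact test of direction, p = 0.0191). That exact test, chosen after the counts were seen, gave p-values from 2.96e-05 to 0.348 over the alternatives. By the same exact test, direction no longer passed without a low-count filter (p = 0.183) or without shCtrl 3 (p = 0.103), shChrebp 3 (p = 0.263), PBS replicate 1 (p = 0.348), the PBS library called a (p = 0.235) or choline replicate 3 (p = 0.270). Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of −0.04 and a Spearman rho of 0.04.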

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

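Some alternatives were chosen after the results were seen. They were edgeR on recovered BMDM reads, lists on log2 CPM of those reads, TMM scaling of FPKM and the row described as Mlxipl. The tests of other splits were also chosen then. The DESeq2 Wald and limma-voom tests in BMDM were planned and were run on recovered reads. Genes called in tumors numbered 3773 to 4334 leaving out 1 library and 2843 to 4819 under alternatives of test, scaling and filter other than a fold minimum. The lowest, 2843, came from limma-trend on FPKM without a filter, which tests more genes at another unit, and a fold minimum of 1 left 351 by its construction. BMDM calls numbered 4867 to 5647 leaving out 1 library and 5490 to 6443 otherwise, and 218 with the fold minimum. Tumor lists called fell from 14 to 1 with an estimated correlation, were 11 to 12 leaving out 1 library and 20 with fry. BMDM lists fell from 7 to 1 with an estimated correlation, rose to 17 with fry, which does not compare a list with other genes, and stayed at 7 without any 1 library. Genes shared in direction numbered 924 to 1135 leaving out 1 library and 958 to 1436 otherwise. The log2 rate ratio of Mlxipl, −0.49, ranged from −1.02 to 0.30 leaving out 1 library and turned positive without shCtrl 1. Its few counts set that range, and the row described as Mlxipl gave −1.20. The value of Chka in tumors, −0.04, ranged from −0.0920 without shCtrl 1 to 0.0089 without shCtrl 2, where it turned positive, and did not pass the threshold. Of 132 tested named tumor genes 117 kept their direction and side of the threshold under each alternative that tested them, the fold minimum aside, and 14 lost it under some. All 19 alternatives tested 121 of the 132, and at least 17 tested the others. Of 120 in BMDM 117 kept both likewise, and Ccl5, ND4L and Rpl30 lost the call under some. All 18 alternatives tested 110 of the 120, and at least 15 the others.

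The tumor replicate numbers did not pair the libraries, since same-numbered libraries had correlations of 0.06, −0.06 and −0.03 across genes. With a replicate block, 4640 tumor genes and 13 lists were called, the glycolysis list being lost, and 1149 genes shared a direction. No block was run in BMDM, because 2 of the PBS columns carry no replicate number and their pairing with choline libraries is not known. A single fit of all 12 libraries was not run, as the tables count different gene models. Of 10 splits of the 6 tumor libraries, the real one called 4505 genes and the highest other 0, and 14 lists against 7. In BMDM the real split called 5754 genes and the highest other 0, and 7 lists against 8, with 6 of 10 splits as large. Such splits are too few for a share under 0.05. Each other split also mixes the groups unequally and keeps part of their difference, so its list count is no null. Of 100 pairs of splits, 1, the real pair, gave 1117 shared genes and the highest other 0. The other splits of each comparison call 0 genes, which fixes that 0, so the pairs do not test the overlap.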

Other observations

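The tests of explanations below were chosen after the results were seen. Beside the lists, the BMDM libraries showed the following levels with PBS, in CPM of recovered reads (SD, n = 3). The osteopontin gene Spp1 was at 5349 ± 222, the chemokine gene Ccl3 at 3428 ± 63.3, the itaconate enzyme gene Acod1 at 3061 ± 38.7 and the lysozyme gene Lyz2 at 2742 ± 58.4. The myeloid genes Csf1r, Itgam and Cd68 were at 787 ± 27.2, 585 ± 11.4 and 431 ± 16.95, and the proliferation gene Mki67 was at 733 ± 12.6. Apoe was at 4.87 ± 0.42 and the mannose receptor gene Mrc1 at 0.0569 ± 0.0003. Irf1 was at 8.66 ± 0.46 CPM. In the tumors, the 12 epithelial genes of the fixed list summed to 92.0 CPM in shCtrl 1 and to 12.3 to 17.2 CPM in the other tumor libraries.

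The row of the tumor table described as Mlxipl held 162 to 501 counts per library and was lower in shChrebp. The tables argue against Mlxipl reads in that row, since the median implied gene length was 4463 bases (4463.1) and the longest annotated Mlxipl transcript has 3622. The row is consistent with S1pr3 reads, the implied length lying within 1 base of the only annotated S1pr3 transcript in 6 of 6 libraries. Where the exchange arose was not tested. Under this hypothesis the table gives a decrease of S1pr3 and no measurable change of the hairpin target.

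Interferon-stimulated genes were lower in shChrebp, their summed level going from 1974 to 774 CPM. A loss of leukocyte transcripts is argued against as the source of the fall. The median over the 77 leukocyte marker genes in shCtrl was 0.102 CPM, while the summed level of the interferon list fell by 1199.6 CPM. These values do not show how many leukocytes the tumors held, since host cells may have been removed before extraction. An effect of fewer leukocytes on the tumor cells through signals was not tested and stays open. Library size or scaling moves every gene alike, and is argued against by a list median that differed from the all-gene median by −1.60. Loss of the hairpin target stays open, because Mlxipl was near absent already in shCtrl and its rate ratio of 0.713 has an interval from 0.141 to 3.31. A hypothesis that the tumor cells themselves may carry a weaker interferon response in shChrebp is left untested, as is which of the hairpin pools departs from unmodified MC38 cells, of which no library was analysed here.

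Both tumor groups held few transcripts of most leukocyte, endothelial, muscle, fat and mast cell markers. With the red-cell list included, 105 of 128 genes from 11 lists were under 1 CPM, with a median of 0.0961 CPM. Of the red-cell markers alone, 2 of 7 were under 1 CPM. The 11 lists leave out fibroblast and keratinocyte markers, which summed to 1690 and 141.6 CPM in shCtrl (Col1a2 at 787 CPM over the 6 libraries). With them 118 of 152 genes were under 1 CPM. A counting step that left most of these genes out altogether is argued against, as 106 of the 128 genes had at least 1 count in some library. So low a bar cannot tell full counting from partial loss, which stays open. Removal of these host cells before extraction could explain it and stays open, since the red-cell list summed to 36.0 CPM, between the bounds of under 1 and over 100 CPM set for the alternatives. The labels call the source tumor tissue, and no sort or culture step is given in the sources used here. These values do not settle whether RNA came from whole tumors or from MC38 cells with few host cells.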
